A study of Drosophila melanogaster with 24 samples.

How the data were processed

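Expression was measured on arrays of 22575 spots in 105 rows and 215 columns, in 24 samples of 6 groups, 4 per group, as given by the sample labels. The deposited scanner tables hold 1 channel per sample, with mean and median signal intensity and mean and median local background intensity per spot, and a quality mark whose meaning is not given, per the file headers and the values. These intensity values are neither background-corrected nor normalized. The authors also deposited a table of values per sample. Set against the scanner tables, it held the natural log of mean signal minus mean background, to within 1e-07, with empty cells where that difference was 0 or below. In replicate order, whose meaning is not given, the sample medians of these natural log values were 4.22, 2.35, 4.17 and 3.13 in female pupae. The medians were 4.33, 3.24, 4.78 and 4.12 in male pupae, and 4.86, 3.78, 2.39 and 4.14 in mixed-sex pupae. They were 3.02, 1.87, 4.96 and 4.79 in embryos, 1.78, 4.10, 1.60 and 4.21 in heads, and 4.33, 2.07, 4.35 and 2.73 in abdomens, so the deposited values are neither centred nor scaled to each other. The natural log values were used only as an alternative. The series design text states that mRNA was labelled without amplification. The software, its version and the steps before scanning are not given in the sources used here. No gene is named for any spot in the tables used here, and a table of 17872 reference genes could not be joined to the spots. The gene-level, splicing and gene-list tests planned from the labels were therefore not run, and the tests were made on probes. The mixed-sex comparison, planned per gene, was also run per probe.

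Identical patterns of marked spots paired each sample with exactly 1 other sample of the opposite dye, which gave 12 arrays of 2 samples. Arrays were called bright or dim by the largest gap in the mean of their median net signals. In R 4.3.3 with limma 3.58.1, the mean signal was corrected for the median local background with normexp and an offset of 50, and log2 values were quantile normalized between samples. Spots with a quality mark above 0, present at 1338 probes in at least 1 sample, were left out. Fold changes are on this log2 scale with the offset, which understates the change of dim probes. A probe counted as detected in a group when its signal exceeded the local background median by 2 SD of the sample's spot backgrounds in at least 3 of 4 samples. All 22575 probes passed in at least 1 group, so this filter removed none. Control spots were not told apart from other spots and were kept.

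One linear model per probe was fitted to all 24 samples with a mean for each group and a dye term, with 17 residual degrees of freedom for complete probes. Variances were moderated by limma with an intensity trend, and the Benjamini-Hochberg adjusted p was called at 0.05. Log2 changes are signed as female minus male pupae, embryos minus mixed-sex pupae, heads minus abdomens, and mixed-sex pupae minus the mean of female and male pupae. The dye term was past the threshold at 1604 probes. Levels printed per group are dye-adjusted means with SD. Probes were named by a rule set before the data were examined. It took up to 2 probes with the largest change in each direction among those past the threshold whose 4 against 4 dye-adjusted values did not overlap. For the mixed-sex comparison it took up to 2 per direction among the 5 smallest p. The text refers to a probe by its number in spot order.

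The model code was tested on simulated data with known changes at a seeded set of the 22575 probes and an intra-array correlation of 0.5. A change of 0.5 log2 units was recovered for 57.4% of probes in the sex, 59.5% in the stage and 61.2% in the tissue comparison. A change of 1 was recovered for 87.7%, 90.6% and 94.3%. Of all calls, 2.37%, 1.81% and 0.585% were false. The simulated noise was independent between probes, while the real samples of an array deviated together across probes. These false shares therefore need not hold for the real data.

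Alternatives set before the data were examined were scaling to the 75th percentile, plain background subtraction, the deposited natural log values, other probe filters, fewer samples in the model, no dye term, a replicate block, the array as a random block, stricter thresholds and leaving out each replicate. Choices made after the data were seen were the exclusion of marked spots, the median rather than the mean background, the SD across spots, and the bright and dim classes. Alternatives added then were the array as a fixed block, the bright or dim class as a term or alone, an offset of 10, the mean background, marked spots kept, and the brighter part of the probes. No slide or scan date was used.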

Results

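RNA of the fruit fly Drosophila melanogaster, isogenic line WI89, was measured on microarrays in 24 samples. They formed 6 groups of 4 samples. The groups were female pupae, male pupae, mixed-sex pupae, mixed-sex embryos, heads of adult males and abdomens of adult males. Pupae were collected as white prepupae, the stage at which the pupal case has just formed, at 0 to 1 h and were then held for 12 h at 25 °C. The mixed-sex pupal samples were made by combining male and female pupal RNA in equal amounts. Embryos came from plates with 24 h of egg laying and so spanned many embryonic ages, and the adult males were 24 to 48 h old. Each group held 2 samples labelled with the dye Cy3 and 2 labelled with Cy5. By its title the series addresses how alternative splicing differs with sex, stage and tissue. Each sample gave the brightness of the same 22575 spots, each read here as 1 probe. The probes could not be tied to genes with the tables used here. Each result below is therefore about probes, a gene can be counted several times, and a change of a transcript's level was not separated from a change of its splicing.

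Median signal over local background ranged from 60.8 to 144 scanner units in the 12 Cy3 samples and from 5.19 to 61.7 in the 12 Cy5 samples. In the Cy3 samples 100% of the probes lay above the detection level, and in the Cy5 samples 74.0% to 100% did. The samples lay on 12 arrays of 2 samples each, and 4 of these arrays were brighter than the other 8. The brighter arrays held 1 sample of female pupae, 3 of male pupae, 2 of mixed-sex pupae, 2 of embryos and none of heads or abdomens. The number of arrays limits the precision of every value. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

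**Figure D1:**
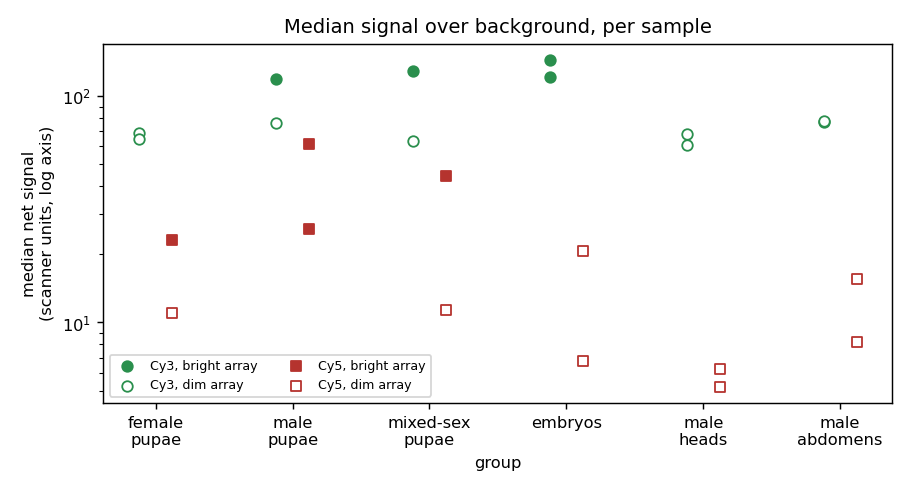
Median net signal (scanner units, log axis) of each of the 24 samples by group, with Cy3 samples as circles, Cy5 samples as squares, and filled symbols for the 4 brighter arrays. Cy3 samples lie between 60.8 and 144 and Cy5 samples between 5.19 and 61.7, with male heads the dimmest in Cy5.

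Female and male pupae were compared to find probes that differ with sex. Of the 22575 probes, 1145 differed, which is 5.07%. Of these, 997 were higher in male pupae and 148 were higher in female pupae, so 87.1% of the differences were toward males. Leaving out 1 sample at a time gave shares between 78.1% and 92.7%. The male-higher probes differed by a median of 0.62 on the log2 scale and the female-higher probes by a median of 0.49. At least 1 log2 unit separated the sexes for 207 male-higher and 8 female-higher probes. At least 2 log2 units did so for 39 male-higher and 0 female-higher probes.

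The largest difference toward males was at probe 3468, whose log2 signal was 6.85 ± 0.60 (SD, n = 4) in female and 10.40 ± 0.16 (SD, n = 4) in male pupae. The change from male to female was -3.55 (SE 0.33, limma adjusted p = 1.72e-07). Probe 20466 followed with -3.39 (SE 0.30, limma adjusted p = 1.02e-07), from 10.25 ± 0.13 in males to 6.87 ± 0.52 in females (SD, n = 4 each). Toward females, probe 8983 had 8.35 ± 0.43 in female and 7.18 ± 0.15 in male pupae (SD, n = 4 each), a change of 1.17 (SE 0.17, limma adjusted p = 8.82e-05). Its change was 1.14 in dim arrays alone (adjusted p = 0.0647) and 0.80 in bright arrays alone (adjusted p = 0.109), each with 1 sample of 1 sex. Probe 19691 had a change of 1.27 (SE 0.37, limma adjusted p = 0.0444), from 11.15 ± 0.32 in males to 12.42 ± 0.50 in females (SD, n = 4 each). This call was lost under 14 of the alternative settings, among them the scaling to the 75th percentile (adjusted p = 0.106), so it rests on the setting. Leaving out any 1 of 7 samples ended it: all 4 male samples and female replicates 1, 2 and 4.

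Over all probes with complete values, called or not, the 4 female and 4 male samples did not overlap for 9.85%. The average over all 35 splits of 8 samples is 2.86%. Samples of an array deviated together across probes, so a single split can exceed this average without a group difference. Female replicate 4 and male replicate 3 lay on the same array. With both left out, 998 probes were called, and the signs on that array matched for 99.1% of the male-higher and 89.9% of the female-higher probes. Male pupae had more samples on bright arrays, and with array brightness as a term 1210 probes differed, 1094 of them higher in males. Dim arrays alone gave 709 probes (703 male-higher) and bright arrays alone 371 (337 male-higher), but with 1 male sample on dim and 1 female sample on bright arrays, which are assumed to vary like the other groups. With the array as a random block 1463 probes differed, 271 of them higher in females and 1192 in males. With it as a fixed block 910 differed, 76 and 834. Scaling to the 75th percentile left 538 probes, 503 of them higher in males.

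**Figure D2:**
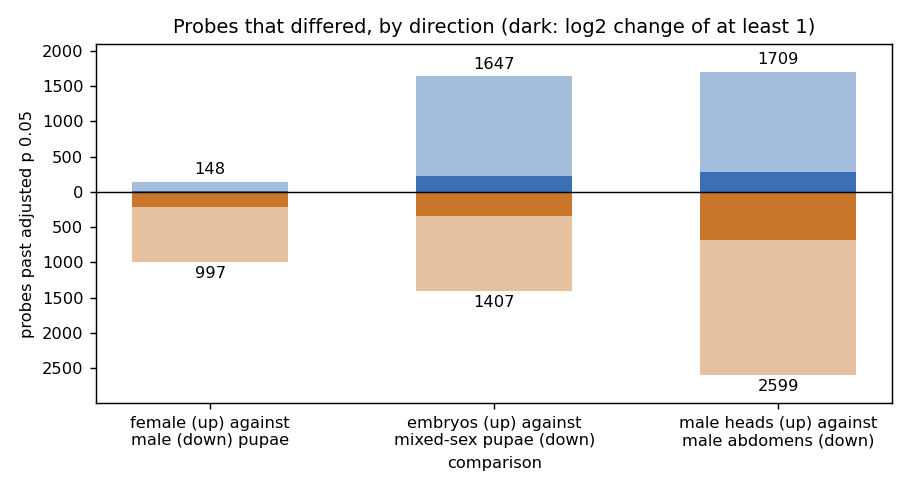
Number of probes past adjusted p 0.05 in each comparison (bars), upward for the group named first and downward for the group named after it, with the dark part for log2 changes of at least 1. The sex comparison has 148 probes upward and 997 downward, and the tissue comparison has the most in all, 1709 upward and 2599 downward.

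Embryos and mixed-sex pupae were compared to find probes that differ with developmental stage. The probes divided more evenly than between the sexes. Of 22575 probes, 3054 differed (13.5%), with 1647 higher in embryos and 1407 higher in pupae. The median size was 0.54 log2 units for embryo-higher and 0.60 for pupa-higher probes. Large differences lay more often toward pupae, with at least 1 log2 unit at 339 pupa-higher and 221 embryo-higher probes and at least 2 units at 103 and 23.

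Probe 19839 had the largest difference, with a log2 signal of 11.17 ± 0.34 in mixed-sex pupae and 6.28 ± 0.20 in embryos (SD, n = 4 each). Its change was -4.88 (SE 0.22, limma adjusted p = 2.96e-12). Probe 2774 changed by -4.78 (SE 0.21, limma adjusted p = 7.17e-12), from 10.99 ± 0.34 in pupae to 6.21 ± 0.22 in embryos (SD, n = 4 each). Neither differed between female and male pupae beyond the error (adjusted p = 0.951 and 0.977). Among the embryo-higher probes, probe 10136 had 10.91 ± 0.45 in embryos and 7.78 ± 0.50 in pupae (SD, n = 4 each), a change of 3.13 (SE 0.23, limma adjusted p = 2.14e-09). Probe 14901 changed by 3.02 (SE 0.40, limma adjusted p = 1.12e-05), from 7.38 ± 0.76 to 10.40 ± 0.31 (SD, n = 4 each).

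Over all probes with complete values, the samples of both groups did not overlap for 17.2%. The average over all splits is 2.86%, which a single split can exceed through deviations shared within arrays. Embryo replicate 3 and mixed-sex pupae replicate 2 shared an array. With both left out, 98.1% of the embryo-higher and 98.5% of the pupa-higher probes had the same sign on that array. With bright arrays alone 1497 probes differed, with dim arrays alone 3264, and with array brightness as a term 3781. With scaling to the 75th percentile 1654 did. The array as a random block gave 3764 and as a fixed block 2667.

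Heads and abdomens of adult males were compared to find probes that differ with tissue. This comparison called the most probes, 4308 of 22575 (19.1%). Of these, 2599 were higher in abdomens and 1709 in heads. The median size was 0.63 log2 units for abdomen-higher and 0.50 for head-higher probes. At least 1 log2 unit separated the tissues at 680 abdomen-higher and 281 head-higher probes, and at least 2 units at 152 and 76.

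Probe 5712 was highest in heads relative to abdomens, with 12.47 ± 0.39 against 6.40 ± 0.78 (SD, n = 3 each after unusable spots were left out). The change was 6.08 (SE 0.40, limma adjusted p = 2.66e-10). Probe 11882 changed by 5.40 (SE 0.42, limma adjusted p = 3.58e-09), from 6.66 ± 0.77 in abdomens to 12.06 ± 0.46 in heads (SD, n = 4 each). Among abdomen-higher probes, probe 10230 changed by -5.94 (SE 0.31, limma adjusted p = 9.89e-12), from 13.02 ± 0.44 in abdomens to 7.08 ± 0.46 in heads (SD, n = 3 each). Probe 323 changed by -5.58 (SE 0.27, limma adjusted p = 8.3e-13), from 13.03 ± 0.33 to 7.45 ± 0.61 (SD, n = 4 each). Both abdomen-higher probes were also higher in male than in female pupae, with sex changes of -3.17 and -3.37 on the log2 scale (limma adjusted p = 8.67e-08 and 2.34e-08).

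**Figure D3:**
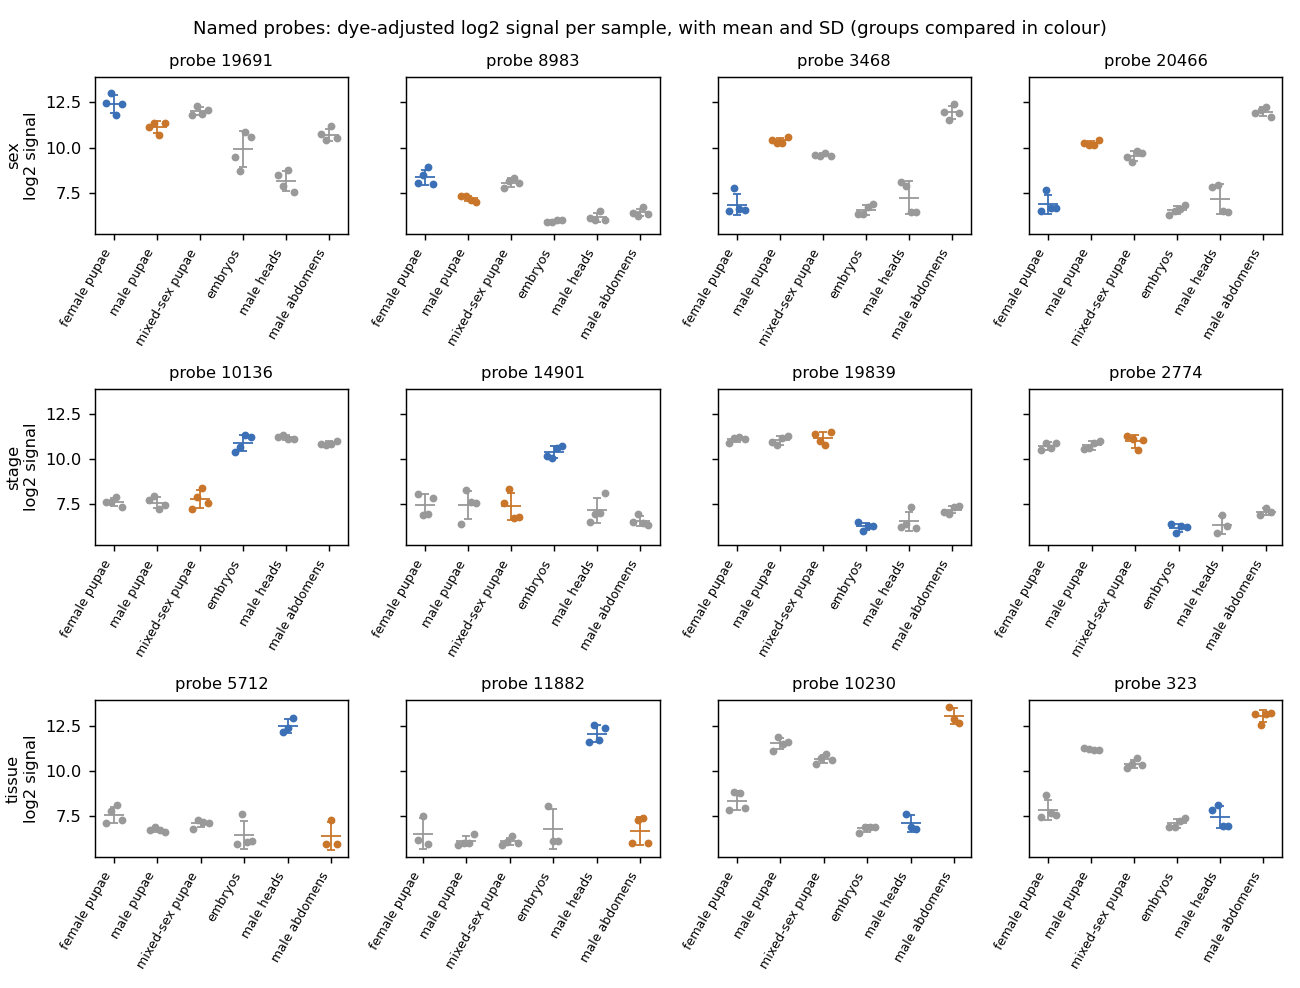
Dye-adjusted log2 signal of the 12 named probes in every sample (points), with the mean and SD per group; the upper panels hold the probes of the sex comparison, the middle panels those of the stage comparison and the lower panels those of the tissue comparison. The groups compared are coloured, and probes 3468 and 20466 of the sex comparison are also high in male abdomens.

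Over all probes with complete values, head and abdomen samples did not overlap for 25.2%. The average over all splits is 2.86%, with the same limit for a single split. On the array that held head replicate 1 and abdomen replicate 3, left out of the calls, 89.2% of head-higher and 96.4% of abdomen-higher probes had the same sign. On that of head replicate 2 and abdomen replicate 2, 96.8% and 98.2% had. All 8 head and abdomen samples lay on dim arrays. The excess toward abdomens depended on the setting: scaling to the 75th percentile called 1579 abdomen-higher and 1502 head-higher probes, and the array as a random block called 3072 and 2886. With the array as a fixed block they were 2596 and 2070.

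The lists of the comparisons shared probes. Of the 997 probes higher in male than in female pupae, 912 (91.5%) were also higher in abdomens than in heads, where 114.8 would be shared by independent lists, and 0 were higher in heads. Across the alternative settings this share ran from 75.8%, with each comparison limited to probes detected in both its groups, to 96.3%, with dim arrays alone. At 75.8% the sex comparison tested 22569 probes and the tissue comparison 19557. Male-higher probes not tested for tissue counted as not shared, which lowered this share. Of these 997, 661 were also higher in mixed-sex pupae than in embryos and 8 were lower, against 62.14 and 72.74 for independent lists. Of the 148 probes higher in female pupae, 85 were higher in mixed-sex pupae than in embryos and 5 were lower, against 9.224 and 10.8. The mixed-sex samples hold RNA of both sexes, so the sex and stage lists are not independent and part of their overlap may be built in. In the tissue comparison 21 of the 148 were higher in abdomens and 15 in heads, where independent lists would share 17.04 and 11.2. Of the 1407 probes higher in mixed-sex pupae than in embryos, 777 were higher in abdomens than in heads, against 162 for independent lists. Of these 777, 645 were also among the 997 male-higher probes, so this overlap is largely that of the male-higher list. For the 1647 probes higher in embryos, 195 were higher in abdomens and 188 in heads, against 189.6 and 124.7. The sex and tissue comparisons share no samples, while 2 pairs of their samples lay on common arrays. Probes are not independent replicates, so these overlaps are given without a p-value.

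**Figure D4:**
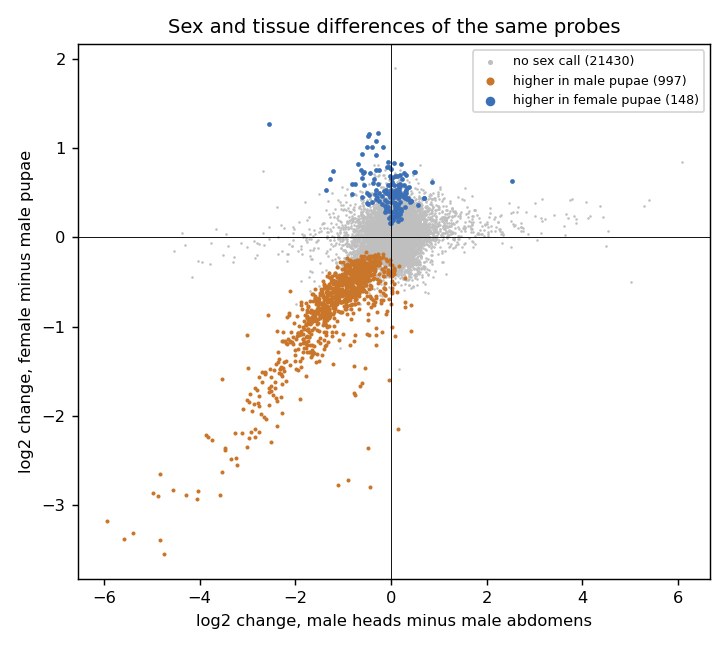
Log2 change of each of the 22575 probes between female and male pupae (vertical) and between male heads and male abdomens (horizontal), with the 997 male-higher and 148 female-higher probes in colour. Most male-higher probes lie on the abdomen side, with 912 of them called higher in abdomens.

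The level of the sex-biased probes was also read in all groups. The 997 male-higher probes had a median log2 signal of 6.06 ± 0.05 in female pupae, 6.75 ± 0.09 in male pupae and 6.52 ± 0.08 in mixed-sex pupae (SD of the sample medians, n = 4 each). The median was 6.06 ± 0.03 in embryos, 6.10 ± 0.06 in male heads and 7.15 ± 0.08 in male abdomens (SD, n = 4 each). The 148 female-higher probes had 7.25 ± 0.12 in female and 6.74 ± 0.11 in male pupae (SD, n = 4 each). They lay between 6.36 and 6.44 in embryos, male heads and male abdomens. The 16385 probes called in none of the comparisons lay between 6.12 and 6.18 in all groups. In female pupae, embryos and male heads the male-higher probes lay below this range, where the offset compresses differences. Female and male pupae were used to choose these lists, and mixed-sex pupae hold RNA of both sexes, so none of the pupal levels is independent of the choice.

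**Figure D5:**
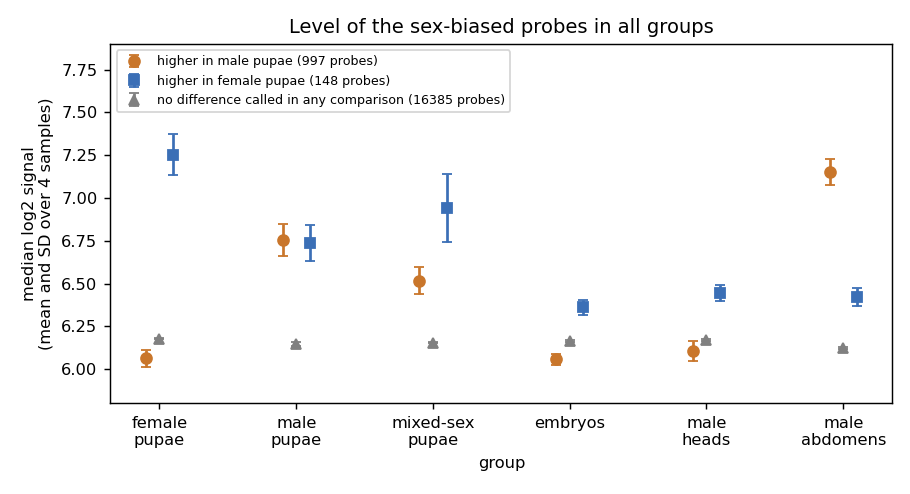
Median log2 signal of the 997 male-higher, 148 female-higher and 16385 uncalled probes in each group (mean and SD of the sample medians, 4 samples per group). The male-higher probes are at 7.15 in male abdomens and 6.10 in male heads, and the female-higher probes are highest in female pupae at 7.25.

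Mixed-sex pupae were compared with the mean of female and male pupae. The mixed samples were made from both RNAs in equal amounts, so no difference is built in at probes equal between the sexes. By limma 1 probe differed, higher in the mixed samples, and 603 probes (2.67%) had an unadjusted p under 0.05. It was probe 18180, with a change of 0.67 (SE 0.09, limma adjusted p = 0.0118) and 8.27 ± 0.09 in mixed-sex, 6.42 ± 0.20 in female and 8.78 ± 0.09 in male pupae (SD, n = 4 each). Probe 7020 followed at 0.61 (SE 0.12) and did not pass (limma adjusted p = 0.185). Both were male-higher probes. A mean of log values lies below the log of an equal mixture, so a positive change at a sex-biased probe is built into this comparison. For the 207 probes at least 1 log2 unit higher in males, the mixed-sex signal lay a median of 0.31 above the mean of the logs and 0.15 above an equal mixture. All 207 lay between the sexes, at a median male share of 0.618 on the linear scale. The share per mixed-sex sample was 0.611 ± 0.143 (SD, n = 4), with a range of 0.486 to 0.789. For the 8 female-higher probes of this size the share was 0.499. Leaving out mixed-sex replicate 2, 3 or 4 ended the single call.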

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

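The tests of bright and dim arrays, of a part of the abdomen, of signal from the other channel and of male RNA in a female sample were chosen or revised after the results were seen. First versions of the last 2 read as favouring both explanations. They were replaced because noise of the same samples entered both sides of the channel test and the male RNA test had no other female samples beside it. In 32 tests for a sample far from the other 3 of its group, 3 stood out, and chance gives about 5% of such tests. At probe 3468, female pupae replicate 2 had a log2 signal of 7.74, against 6.49 to 6.60 in the other female samples. At probe 20466 the same sample had 7.64, against 6.50 to 6.67. At probe 323, male abdomen replicate 2 had 12.53, against 13.17 to 13.22 in the other abdomens.

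Both female outliers are at male-higher probes. Over the 223 probes called at least 1 log2 unit higher in males without this sample, female replicate 2 lay a median of 0.0845 of the way to the males, against -0.0526 to 0.0036 for the other female samples treated alike. A raised floor in a dim sample was argued against: sex-neutral probes of matched signal deviated by -0.0299 log2 units, against 0.23 at the male-higher probes. Male RNA in the sample stays open. Female-higher probes were lowered by 0.0878 of the sex difference, but other female samples gave 0.0646 to 0.661, so this does not separate it. Signal from the other channel of the array could be involved. The slope of each sample's deviation on the difference between another group and its own was taken. Of 12 Cy5 samples, 6 followed the group on their other channel most closely, where chance gives 2.4. Of the 12 brighter Cy3 samples 6 also ranked that group first, but embryo replicate 4 had a slope of -0.019 and head replicate 2 of 4.4e-05. Female replicate 2 shared its array with mixed-sex pupae, which hold male RNA. It followed that group most closely (slope 0.049, against -0.013 for male pupae). Female replicate 4, which shared an array with male pupae, lay 0.0036 of the way to the males. No biological explanation was tested.

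More probes were higher in male than in female pupae, 997 against 148. An imbalance of bright and dim arrays was argued against as the whole cause, since 90.4% of the calls were male-higher with array brightness as a term. Scaling to the 75th percentile gave 93.5% and an offset of 10 gave 89.9%, which argues against both choices. Of the 35 splits of the 8 pupal samples, 1 gave as many calls, the real one with 1145. The highest other gave 812, the split that parts bright from dim arrays. These totals count both directions, so they do not test the excess toward males. Sex itself remains a hypothesis for the excess, found and examined on the same samples.

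The same split count was made for the other comparisons. The smallest share it can give is 1 of 35, so it does not exclude chance. Mixed splits also leave the real group difference in the residual spread, which lowers their calls. For embryos against mixed-sex pupae 1 of 35 splits reached the real 3054 calls, and the highest other, 2137, again parted bright from dim arrays. For heads against abdomens 1 of 35 splits reached 4308, and the highest other gave 58.

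Male-higher pupal probes were largely abdomen-higher as well. Arrays shared between the comparisons were argued against, since 86.5% of 734 male-higher probes were abdomen-higher without the 4 samples on such arrays. Probe brightness was argued against too, since 8.75% of sex-neutral probes of matched signal were abdomen-higher. A part of the abdomen that yields more RNA in male than in female pupae is a candidate explanation. It predicts that all 997 male-higher probes, a list chosen without the abdomen samples, are brighter in abdomens than in whole male pupae. Their median difference was 0.431 log2 units and 88.9% were brighter, against 45.2% of all probes, while abdomen-higher probes with no sex call had 0.32 and 90.6%. The probes with no sex call met the prediction too, so it does not separate this explanation from higher abdomen signal alone. Abdomens and pupae differ in age as well, which was not tested, so the explanation remains a hypothesis.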

How the results depend on the processing

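Results within array brightness classes, with fixed array blocks, an offset of 10, the mean background, marked spots kept and brighter probes were chosen after the data were seen. No main call was called in the opposite direction under any setting run. Main calls that lost the threshold under a setting were not checked for direction. With scaling to the 75th percentile, 538 probes differed with sex, 1654 with stage, 3081 with tissue and 0 in the mixed-sex comparison. Of the 3081, 1579 (51.2%) were abdomen-higher against 60.3% of the main calls, and 2424 were also main calls. The median change of all probes, 0.023 and 0.047 in the main values, lay 0.17 toward females and 0.22 toward heads under that scaling. Relative to the medians under that scaling, its called probes had a median log2 change of 0.50 and -1.14 for sex. For tissue the values were 0.22 and -1.13. Dim arrays alone gave 709 for sex and 0 for the mixed-sex comparison; bright arrays alone gave 371, 1497 and 0. For sex each rests on 1 sample in an arm, assumed to vary like the other groups. A log2 change of at least 1 left 215, 560, 961 and 0. The mixed-sex comparison had 0 calls with only the samples compared, a fixed array block and adjusted p under 0.01, 8 with a random array block and 7 with an offset of 10. Fewer samples or stricter thresholds account for part of these; for the others the cause was not tested.

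Leaving out 1 replicate gave 959 to 1226 calls for sex, 2542 to 3031 for stage, 3685 to 4281 for tissue and 0 to 1 for the mixed-sex comparison. The female-higher count, 148 in the main calls, was least stable. It was 269 without female replicate 4 and 237 without male replicate 1. Female replicate 4 was the only female sample on a bright array, and male replicate 1 the only male sample on a dim array. Leaving out either parted the sexes further by array brightness. Female replicate 4 lay a median of 0.661 of the way to the males at those 269 probes. The count was 88 without female replicate 2 or male replicate 2, 92 without female replicate 3 and 76 without male replicate 4. It was 99 without male replicate 3, 116 with array brightness as a term and 52 with only the female and male pupal samples. With the array as a random block (correlation 0.489) 1463, 3764 and 5958 probes differed with sex, stage and tissue, and as a fixed block 910, 2667 and 4666. With a replicate block 1085, 2895, 4147 and 1 probes were called. Correlations of same-numbered deviations ran from -0.483 to 0.72 and gave no regular pairing by number. Deviations shared within arrays enter these correlations, so they cannot show whether the numbers mark a shared source. Of 292 values of named probes, 276 kept their call and 16 lost it, 14 of them at probe 19691. Removing the detection filter changes nothing. Gene, splicing and list alternatives and slide or scan date were not run, and heads were not on bright arrays. Low Cy5 signal over background, 5.19 at the lowest, limits dim probes.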

Other observations

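Male heads differed among themselves at abdomen-higher probes, which was noticed after the values were seen. At probe 3468, heads of replicates 1 and 2 had log2 signals of 8.11 and 7.89, and those of replicates 3 and 4 had 6.44 and 6.41. At probe 20466 the values were 7.81, 7.92, 6.46 and 6.42. Head replicates 1 and 2 were on arrays with abdomen samples, and replicates 3 and 4 were not. Over abdomen-higher probes of at least 2 log2 units, called without the head sample in question, replicates 1 and 2 lay 2.25% and 2.71% of the way from the other heads to the abdomens. Replicates 3 and 4 lay at -2.08% and -2.51%. These values were not tested further.

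Samples of one array deviated together from their group means. The correlation across probes was above 0 in 12 of 12 arrays, from 0.136 to 0.605, and probes are not independent replicates. After group and dye were removed, the leading component held 38.6% of the residual variance. Its mean score was 0.207 on bright and -0.104 on dim arrays, and dim arrays ranged from -0.283 to 0.103. Its loadings had r = 0.0308 between neighbouring spots and rho = 0.0272 with probe signal. Tests of array brightness, spot position and probe signal as its source were run and set aside after their values were seen, in favour of another pattern; the first was chosen after the component was seen. The bright arrays scored from 0.127 to 0.252, so each of the 4 lay above every dim array. The range of the dim arrays, 0.386, exceeded the gap between bright and dim means, 0.311, and both correlations were near 0. The source stays open.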
